A study of Mus musculus with 6 samples.

How the data were processed

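Total RNA of mouse embryonic stem cells was extracted with Trizol, amplified and biotin-labelled with a linear amplification kit, and read on Illumina MouseRef-8 bead arrays by the authors. The cells were grown in medium with serum and LIF and without feeder cells, and were harvested after 5 days. One chip held all 6 arrays, so no chip or date batch could be separated. The labels give 2 Sox17-inducible lines that were derived independently and the control line KH2, each with and without doxycycline at 1 µg/mL. The line whose label carries no number was taken as line 1. Arrays of a line were treated as a pair because the labels name the line. As a check, the difference between line 1 and line 2 was computed with and without doxycycline, and both differences correlated with r = 0.509 across 12373 probes. Between arrays, induced line 2 correlated most with its own untreated array (0.989), but induced line 1 correlated with untreated line 2 (0.986) more than with its own untreated array (0.983), so the values alone do not settle the pairing. The fits in the report do not use the pairing unless the line is named as a block.

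The deposited table of raw values holds, per the file headers, the mean bead signal of each probe as an intensity on a linear scale with no normalization seen, its bead standard error as an intensity, the number of beads, and a detection p_value. The detection p-value in the deposited table is the share of negative control bead types at least as bright as the probe. A second deposited table holds intensity values that the authors had background-subtracted and normalised in BeadStudio, whose version is not stated, by a method that is not stated. In each array their order was that of the raw values (rank correlation 1), their medians were 25.6 to 34.1, and the lowest was -34.7. The median number of beads per probe was 38 to 40 and the median bead standard error was 4.51% to 4.79% of the signal. Signal over background limited what could be read: 43.7% to 46.5% of the probes were detected on an array.

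Raw signal was background-corrected by the normexp model with the negative-control background inferred from the detection p-values, given an offset of 16, quantile-normalised between the 6 arrays and set on the log2 scale (neqc in limma 3.58.1 under R 4.3.3). Of 25697 probes, 12373 with a detection p under 0.05 on at least 2 arrays were tested. A gene was read by its brightest tested probe, which gave 8605 genes, 2210 of them with several tested probes. Gene symbols are those of the table, checked by Entrez number against a mouse gene table that was used for names only; 16 numbers were not matched, and 1719 probes, 710 of them tested, had no symbol. No genome build or probe position was given, and none is used here.

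Each comparison was a contrast in limma (lmFit and eBayes, two-sided, Benjamini-Hochberg over the probes tested, threshold 0.05) with a mean for each of the 4 groups. This leaves 2 residual degrees of freedom, both from the inducible lines, so the single KH2 arrays were assumed to vary like them. The comparison with all uninduced arrays used 2 means and 4 residual degrees of freedom. The KH2 pair was described by the number of probes at least 2-fold apart. Where a group had no detected array, a bound was computed against the detection limit in place of a fitted fold change. Correlations of changes are across genes.

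Before the data were examined, 24 gene lists were written from textbook knowledge: parietal endoderm, visceral endoderm, extraembryonic endoderm core, basement membrane, pluripotency, primed epiblast, mesendoderm and definitive endoderm, mesoderm, neuroectoderm, trophoblast, endothelial, fibroblast and feeder cell, germ cell, epithelial junction, cell cycle, p53 and apoptosis, Wnt targets, Nodal targets, FGF targets, amino acid and mitochondrial stress, endoplasmic reticulum folding and secretion, cholesterol synthesis, glycolysis, and ribosomal protein. Each had at least 3 tested genes. Lists were tested by limma's camera with a preset inter-gene correlation of 0.01, by camera with an estimated correlation, and by fry, with Benjamini-Hochberg adjustment over the 24 lists. camera compares a list with all other tested genes, and fry asks whether a list's genes move one way. With an estimated correlation, camera takes its p from the few residual degrees of freedom, so a call was hard to reach whatever the correlation. The FGF target list of the third comparison had an estimated correlation of -0.043, below the preset, yet its unadjusted p went from 0.0073 to 0.0487. A call lost this way does not show that a list's genes varied together. The lists called in the first comparison had estimated correlations of 0.081 (FGF target) to 0.661 (cholesterol synthesis), all above the preset. For these lists the p-values with the preset assume less shared variation than was estimated. The loss of their calls cannot be split between correlation and degrees of freedom. Members were also counted with the adjustment over the list alone.

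The rule for named genes was fixed beforehand. It took genes past the threshold that changed the same way in both inducible lines, or, where too few passed, the largest changes among genes at least 2-fold changed the same way in both, up to 12 in each direction. As none passed in the first 3 comparisons, all genes named by it are given as sizes. It also took Sox17, Sox7, Sox18, Actb, Gapdh, Hprt and Tbp, up to 4 members of each list with the largest changes, and the 6 largest changes each way in KH2. Genes outside the rule are said to have been chosen after their values were seen.

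The fit was tested on simulated data with variances drawn around the spread that limma estimated from these arrays. Noise was independent between probes and arrays, without differences between lines. Each draw held 200 changed probes, 50 at each of 2-, 4-, 8- and 16-fold, and the larger changes ease the adjusted threshold for the rest. The fit was run in this setting only, and the shares it recovered need not hold for the real arrays. Of 4-fold changes it recovered 87.8% in the first comparison, 69.6% in the second, 96.1% in the third, 7.8% in the fourth and 66.2% in the fifth, and of 2-fold changes 9.1%, 1.9%, 38.6%, 0.2% and 1.8%. With the preset correlation and simulated genes that vary independently, a list of 12 genes raised by 0.9 reached an unadjusted p under 0.05 in 100% of 100 draws, and an untouched list in 4%; recovery with an estimated correlation was not simulated. Alternatives were quantile normalization without normexp, normexp with median centring, the authors' values floored at 16, no filter and a stricter filter (detection p under 0.01) on dim probes, trend and robust moderation, the line as a block with and without a doxycycline term, only the arrays of the inducible lines, the mean of a gene's probes, another fold minimum of 1.5 and a pooled-spread test for KH2, and each array left out in turn. The effect of these on list counts beyond the first comparison, and on the counts of genes changed in both lines, was added after seeing the data, as was the line block for the difference of responses.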

Results

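Gene expression was measured in cultured mouse embryonic stem cells that carried a doxycycline-inducible Sox17, a transcription factor of the SoxF family that is active in extraembryonic and definitive endoderm. The data were 6 bead arrays on 1 chip. They covered 2 independently derived Sox17-inducible lines, each with doxycycline (Sox17_dox, n = 2) and without it (Sox17_untreated, n = 2). The control line KH2 was also measured with doxycycline (KH2_dox, n = 1) and without it (KH2_untreated, n = 1). Doxycycline, a drug that switches the inducible gene on, was given at 1 µg/mL for 5 days. Each array read 25697 probes, of which 11219 (KH2_dox) to 11957 (Sox17_untreated of line 1) were detected above the negative controls. Array medians of raw signal ran from 109 to 129 intensity units. Correlations of normalised signal across probes between pairs of arrays ran from 0.968 to 0.989. The number of arrays limits the precision of each value, and the KH2 values had no replicates. Changes are given on the log2 scale of normalised signal as dox minus untreated within a line, and fitted differences carry their standard error (SE).

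Sox17 itself read near the background on these arrays. Its brighter probe read 5.26 without and 5.61 with doxycycline in line 1, 5.60 and 6.47 in line 2, and 5.20 and 5.31 in KH2. That probe was above detection only on the induced line 2 array, and the second Sox17 probe was above detection on no array. The position of these probes in the transcript was not given, so a transcript from the inducible construct need not carry their target, and these values do not check the labels. Both probes were too dim to be tested. Of the SoxF relatives, the Sox7 probe with the larger differences was detected on 1 Sox17_dox array only and was not tested. Sox18 was detected on neither induced array, at least 1.21-fold below the untreated lines, and did not pass the test. The housekeeping genes Gapdh (-0.05, 0.05 and 0.03) and Tbp (-0.44, 0.03 and -0.09) stayed within 0.5, as did the brightest Actb probe (0.09, -0.01 and -0.04), and Hprt had values of -0.33, -0.27 and -0.56. Other Actb probes gave larger changes, up to 2.07 in line 1.

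The first comparison asked which genes differed between the Sox17-induced lines and the same lines without doxycycline. Gata6, a transcription factor that specifies primitive endoderm, was higher with doxycycline by 2.18 in line 1 and 1.94 in line 2, against 0.29 in KH2. Pdgfra, a receptor found on primitive endoderm cells, was detected on both induced arrays and on no other array, at least 1.64-fold above the untreated lines. Type IV collagen and laminin genes of the basement membrane were higher in both lines, with Col4a1 at 1.66 and 0.95 and Lama1 at 1.88 and 0.37. Spink1, which encodes a secreted trypsin inhibitor, was lower in both lines (-1.46 and -2.10), as were the Nodal inhibitors Lefty1 (-1.49 and -1.02) and Lefty2 (-1.34 and -1.02). The transcripts of the core pluripotency factors, named here after their values were seen, differed little, with Pou5f1 at 0.20 and 0.19, Nanog at -0.09 and -0.05, and Sox2 at -0.16 and -0.20.

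None of these single genes passed the test. limma called 0 of 12373 probes at an adjusted p under 0.05, with a smallest adjusted p of 0.955, and 0 with trend and robust moderation. An unadjusted p under 0.05 was reached by 528 probes, where chance would give 619. With the line as a block, 914 probes reached it and 1 passed, that of Gata6 (log2 change 2.06, adjusted p = 0.0437). With an added doxycycline term, which takes off the response of KH2, 1262 reached it and 0 passed (smallest adjusted p = 0.482). Values that were large in both lines are therefore given below as sizes. Of 8605 genes, 13 were at least 2-fold higher in both lines, where 0.545 would be by the product of the lines' shares. Another 10 were at least 2-fold lower in both, where 0.447 would be. These products take the lines' changes as independent and all genes as equally variable, so the excess over them is not a measure of induction. Changes in line 2 also correlated with those in KH2 (Pearson r = 0.280, against 0.328 between the inducible lines). Neither set held a gene that was 2-fold changed the same way in KH2, and the counts were 4 and 1 without background modelling and 17 and 29 in the authors' values. The sets include Pdgfra and Zscan5b, whose lower levels were below detection.

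Among the 12 largest of the higher genes, Gata6 had a mean change of 2.06 ± 0.59 (SE, n = 2 arrays against 2). Fbp2, a gluconeogenic bisphosphatase, followed with 1.65 ± 0.77 and read -0.48 in KH2. Fbln2, an extracellular matrix protein, had 1.29 ± 0.20 and the choline transporter gene Slc44a1 1.23 ± 0.22. The secreted protease gene Htra1 was higher by 1.64 and 1.01 (0.60 in KH2), and the forkhead gene Foxq1 by 1.29 and 1.10. Stard8, Rab3il1, Rapgef3 and Hbegf were each higher by between 1.00 and 1.49 in both lines. Hbegf, a growth factor of the EGF family, was also higher by 0.76 in KH2. Tbx3 was higher by 1.31 and 1.11 by its brightest probe, while its other probes gave 0.04 and 0.46, and 0.89 and 0.65. Other probes of Fbln2 (0.85 and 1.14), Htra1 (1.71 and 0.70) and Stard8 (0.97 and 1.20) were each under 2-fold in 1 line, and read -0.03, 0.79 and 0.86 in KH2, where the brightest Stard8 probe read 0.46. The lines differed in level before induction: Gata6 read 6.25 in untreated line 1 and 7.77 in untreated line 2, and 8.43 and 9.71 with doxycycline.

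Among the 10 lower genes, Spink1 had a mean change of -1.78 ± 0.39 (SE, n = 2 against 2), against 0.24 in KH2. Pla2g1b, a secreted phospholipase, had -1.53 ± 0.38, with -2.04 in line 1 and -1.03 in line 2. Alox5ap, needed for leukotriene synthesis, had -1.50 ± 0.23 and read -0.40 in KH2. Cntnap2 had -1.28 ± 0.19, and Actn3 read -1.28 and -1.23 with 0.00 in KH2, while its other probes gave -1.47 and -1.40, and -1.29 and -0.55. The histone gene H3c7 (-1.14 and -1.24), Rab33a (-1.06 and -1.04), both Lefty genes and Zscan5b completed the set. Zscan5b was undetected on both induced arrays, at least 1.28-fold below the untreated lines. Lefty2 also read -0.92 and Zscan5b -0.84 in KH2 cells given doxycycline.

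**Figure D1:**
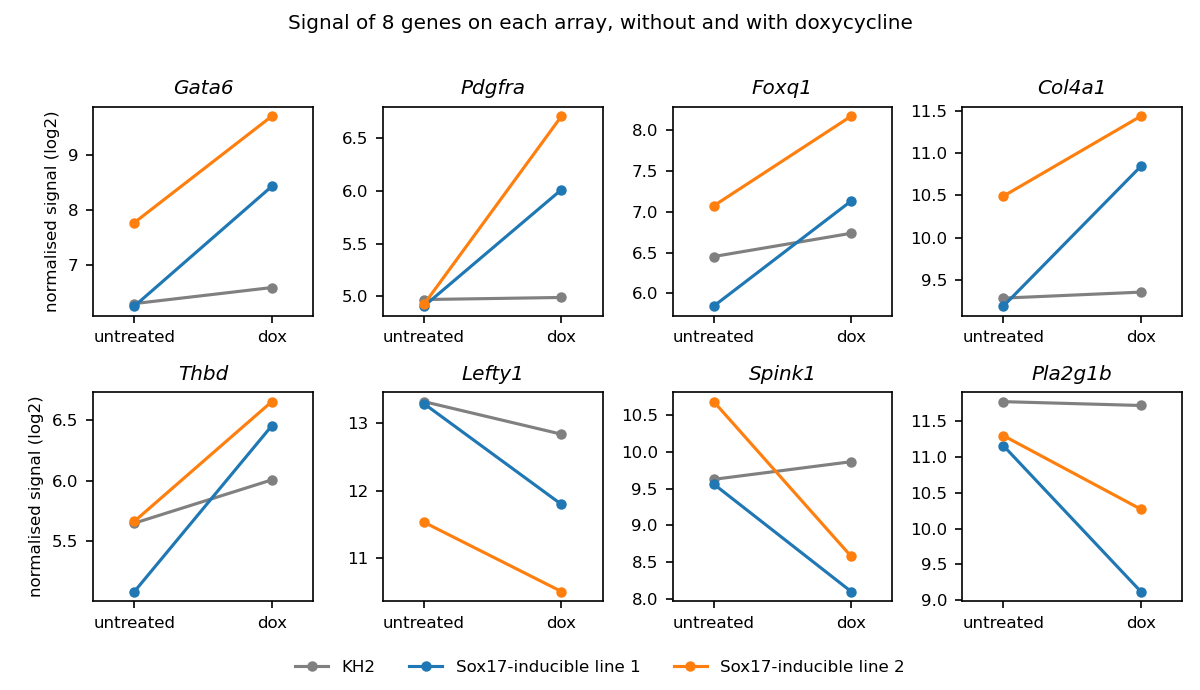
Normalised signal (log2, vertical axis) of 8 genes on each of the 6 arrays, without and with doxycycline (horizontal axis), with a line joining the pair of arrays of KH2 (grey), Sox17-inducible line 1 (blue) and line 2 (orange); vertical axes differ between genes and do not start at 0. Gata6 goes from 6.25 to 8.43 in line 1 and from 7.77 to 9.71 in line 2, against 6.29 to 6.59 in KH2, and Spink1 goes from 9.56 to 8.10 and from 10.68 to 8.58, against 9.62 to 9.86.

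Gene lists had been fixed before the data were examined. All 12 tested genes of the extraembryonic endoderm core list were higher on average in the induced lines, with a median of 0.90, or 0.73 with the undetected Pdgfra levels at their bound and 0.56 without the untreated array of line 1. The list was higher than other genes at an adjusted p of 5.0e-08 with the preset inter-gene correlation and 0.631 with an estimated correlation. Its median was 0.99 in line 1, 0.81 in line 2 and 0.13 in KH2. The parietal endoderm list, whose members include Thbd (1.37 and 0.99) and Foxq1, was higher for 13 of 14 genes (median 0.65, adjusted p = 1.38e-07, and 0.631 with an estimated correlation), with a median of 0.34 to 0.93 when an array was left out. It was higher in KH2 with doxycycline too, with a median of 0.28 and 12 of 14 genes higher, against medians of 0.68 in line 1 and 0.54 in line 2. Against KH2_dox its median difference in the induced lines was 0.05. The basement membrane list was higher for 15 of 16 genes (median 0.51, adjusted p = 1.58e-07, and 0.631 with an estimated correlation), with Col4a2 at 1.27 and 0.90 and the nidogen gene Nid1 at 0.97 and 0.71. These 3 lists share members such as Lama1 and Sparc, so their calls are not independent. The visceral endoderm list was not called (median 0.14, adjusted p = 0.0746): the apolipoprotein gene Apoe was at 0.78 and 0.51, Apom at least 1.26-fold above the untreated lines, where it was undetected, and the endocytic adaptor gene Dab2 at -0.07 and 0.72.

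Other lists were also called with the preset correlation. The amino acid and mitochondrial stress list was higher for 12 of 13 genes (median 0.54, adjusted p = 6.1e-06, and 0.631 with an estimated correlation). Its median was 0.89 in line 1, 0.14 in line 2 and 0.22 in KH2, with the difference between the lines not tested, and it was 0.24 without the untreated array of line 1. Its members Ddit3, a stress transcription factor, and Trib3, a pseudokinase induced with it, read 2.29 and 0.98, and 1.77 and 0.40, while the glutathione-degrading enzyme gene Chac1 read 1.97 in line 1 and -0.12 in line 2. The FGF target list was higher for 8 of 10 genes (median 0.25, adjusted p = 0.0184, and 0.631 with an estimated correlation), with the phosphatase gene Dusp4 at 1.37 and 0.46 and Phlda1 at 0.62 and 1.25. The fibroblast and feeder cell list was higher for 6 of 7 genes (median 0.59, adjusted p = 0.00475, and 0.631 with an estimated correlation), with the call lost without the induced array of line 2 (median 0.25) and a median of 0.13 with no filter on dim probes. Its members Lox (1.25 and 0.39), Col5a1 (0.64 and 0.69) and Acta2 (0.73 and 0.66) encode matrix and contractile proteins that are not limited to fibroblasts. In KH2, Acta2 read 0.34 by that probe and 1.11, 0.91 and 0.89 by its other probes, against -0.21 for Lox and -0.02 for Col5a1, and the cultures held no feeder cells per the labels. The cholesterol synthesis list was lower for 7 of 8 genes (median -0.38, adjusted p = 0.00326, and 0.736 with an estimated correlation), with Insig1 at -1.17 and -0.24 and Hmgcs1 at -0.79 and -0.24. The median of this list was -0.66 in line 1, -0.11 in line 2 (4 of 8 genes higher) and -0.07 in KH2, with the difference between the lines not tested. In KH2, Hmgcs1 read -0.84 and Insig1 -0.47, with -0.56 and -0.65 by the other Insig1 probes. The cell cycle list was lower for 8 of 10 genes (median -0.20, adjusted p = 0.0499, and 0.736 with an estimated correlation), with Pcna at -0.48 and -0.32. That call was also lost in the authors' values and without either KH2 array or the induced array of line 2. The median of the cell cycle list was -0.27 in line 1, -0.11 in line 2 and -0.11 in KH2. Its member Ccne2 was undetected on both induced arrays and on the KH2_dox array. On the induced arrays it was at least 1.46-fold below the mean of the untreated lines, a bound that need not hold for each line.

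The pluripotency list was not called, with a median of 0.05 over 23 genes (adjusted p = 0.497). Within it, Dppa3 read -0.23 and -1.39, Nr5a2 -0.58 and -0.68, and Stat3 0.60 and 0.58, with 0.33 and 0.26, and 0.59 and -0.04, by its other probes. In KH2 the brightest probes of Nr5a2 and Stat3 read -0.36 and 0.32. The other Nr5a2 probe read -0.78 and -0.60 in the inducible lines and -0.71 in KH2. Tbx3, given above, is a member of this list too. Lists of other germ layers and lineages were not called either. Their medians were -0.07 for primed epiblast (adjusted p = 0.896), -0.30 for mesendoderm and definitive endoderm (0.262), 0.18 for mesoderm (0.417) and -0.11 for neuroectoderm (0.670). The trophoblast (0.01, adjusted p = 0.767), endothelial (0.21, 0.767) and germ cell (0.23, 0.914) lists were likewise not called. Only part of each list was tested: 3 of 14 genes for mesendoderm and definitive endoderm, 3 of 14 for mesoderm and 3 of 12 for germ cell. For neuroectoderm 7 of 14 were tested, for primed epiblast 7 of 13, for trophoblast 9 of 16 and for endothelial 10 of 16. With so few genes, a list not called does not show that a lineage did not respond. Adjusted over the list alone, 2 genes of the parietal endoderm list and 1 of the core list passed, and 0 of the other called lists. With an estimated correlation 0 of 24 lists were called (lowest adjusted p = 0.631), and by fry 0 (0.623). The estimated-correlation p rests on 2 residual degrees of freedom, so that loss cannot tell shared variation from the small number of arrays. Leaving out the untreated array of line 1 cut the called lists from 8 to 4, as the FGF target, fibroblast, cholesterol and cell cycle lists were lost (medians 0.15, 0.26, -0.17 and -0.10), and with the line as a block 10 were called.

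**Figure D2:**
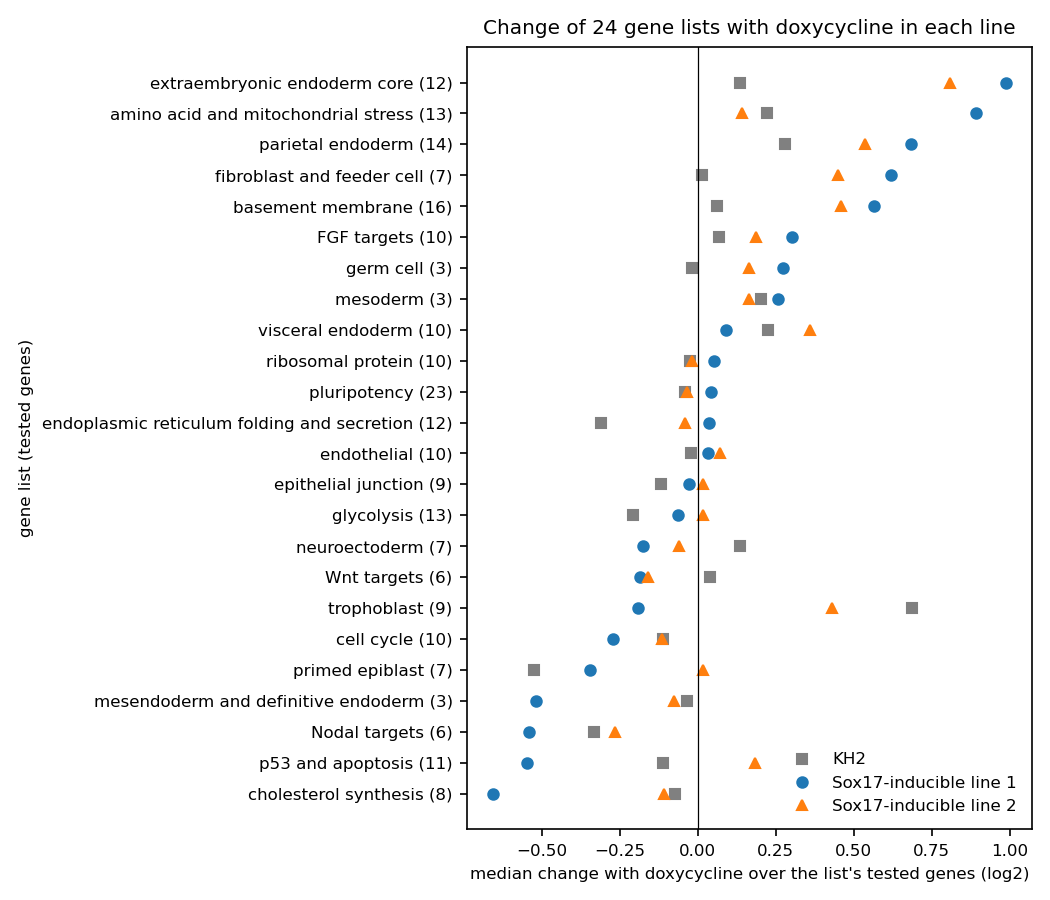
Median change with doxycycline over each list's tested genes (log2, horizontal axis) for the 24 gene lists (vertical axis, number of tested genes in brackets) in KH2 (grey squares), Sox17-inducible line 1 (blue circles) and line 2 (orange triangles). The extraembryonic endoderm core list lies at 0.99 and 0.81 in the inducible lines and at 0.13 in KH2, while the trophoblast list lies at 0.69 in KH2, -0.19 in line 1 and 0.43 in line 2.

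The second comparison set the induced lines against KH2 cells that also had doxycycline, so that the drug was present on both sides. Differences between the lines and KH2 before induction are included in it, and only the fourth comparison takes them off. Gata6 was higher in the induced lines by 2.48 ± 0.72 (SE, n = 2 against 1), Fbp2 by 2.73 ± 0.95 and Col4a1 by 1.79 ± 0.54. Pdgfra was at least 1.44-fold higher. Pla2g1b was lower (-2.02 ± 0.46), as were Lefty1 (-1.68 ± 0.78) and Spink1 (-1.53 ± 0.48). Otx2, a transcription factor of the epiblast and anterior neural plate, was higher by 2.19 ± 0.29, with changes on doxycycline of 0.88 in line 1, 0.25 in line 2 and -1.26 in KH2. Fgf8, expressed in the gastrulating epiblast, was detected in KH2 and on no array of the inducible lines, at least 2.46-fold lower in the induced lines.

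The extraembryonic endoderm core list was the only list called as higher here, with 10 of 12 genes higher (median 0.90, adjusted p = 0.00762, and 0.743 with an estimated correlation). Called as lower, each with an adjusted p of 0.743 with an estimated correlation, were the Wnt target list (6 of 6 genes lower, median -0.77, adjusted p = 0.00143), with Cdx1 at -1.52 ± 0.50 and Myc at least 1.65-fold lower, the mesendoderm list (3 of 3 genes, median -1.08, adjusted p = 0.0107), with Gsc at least 1.42-fold lower, and the trophoblast list (7 of 9, median -0.74, adjusted p = 0.0137). The trophoblast list held the simple-epithelium keratin genes Krt19 (-2.15 ± 0.47) and Krt7 (-1.68 ± 0.42). Adjusted over the list alone, 4 Wnt targets, 2 mesendoderm genes and 2 trophoblast genes were lower, and 0 core list genes were higher. These lists were also lower in the untreated inducible lines than in untreated KH2. By limma 0 probes passed (smallest adjusted p = 0.293, with 1370 at an unadjusted p under 0.05 and 0 with trend and robust moderation), and by fry 0 lists (lowest adjusted p = 0.152). Leaving out either untreated inducible array raised the called lists from 4 to 7.

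The third comparison set the induced lines against all 4 uninduced arrays together. Gata6 was higher by 2.34 ± 0.46 (SE, n = 2 against 4), Col4a1 by 1.56 ± 0.36 and Slc44a1 by 1.15 ± 0.19. Alox5ap was lower (-1.43 ± 0.21), as were Pla2g1b (-1.79 ± 0.32) and Actn3 (-1.40 ± 0.34). Of 9 called lists, each of which had an adjusted p of 0.302 or more with an estimated correlation, 6 were higher and 3 lower. Those higher were the extraembryonic endoderm core (12 of 12 genes, median 0.96, adjusted p = 4.83e-09), parietal endoderm (12 of 14, 0.45, 7.41e-06), visceral endoderm (8 of 10, 0.14, 0.0323) and basement membrane (14 of 16, 0.43, 8.95e-07) lists. The FGF target (8 of 10 genes, median 0.28, adjusted p = 0.0219) and amino acid stress (12 of 13, 0.52, 7.41e-06) lists were higher too. Those lower were the Wnt target (6 of 6 genes, median -0.47, adjusted p = 0.00684), Nodal target (6 of 6, -0.38, 0.0192) and cholesterol synthesis (7 of 8, -0.39, 0.00598) lists. The Wnt and Nodal target lists were not called within the inducible lines (adjusted p = 0.497 and 0.302) and were lower in them than in KH2 before induction (medians -0.60 and -0.62), a difference that this comparison, which ignores the line, includes. By fry 0 were called (lowest adjusted p = 0.165). Adjusted over the list alone, 7 core, 6 parietal endoderm, 4 basement membrane, 1 visceral endoderm, 1 FGF target and 1 stress gene were higher. In a permutation of the core list's mean per array, the 2 induced arrays were the highest of the 15 possible splits of 6 arrays (two-sided exact p = 0.0667, the smallest these splits allow). These splits exchange arrays across lines and do not use the pairing by line. Over all probes limma called 0 (smallest adjusted p = 0.364, with 945 at an unadjusted p under 0.05, and 0 with trend and robust moderation). Without the untreated array of line 2 it called 24 probes, 15 higher and 9 lower, Gata6 among them (2.69, adjusted p = 0.0316). With the line as a block this contrast is that of the first comparison (Gata6 2.06, adjusted p = 0.0437), whose call is lost with an added doxycycline term.

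The fourth comparison tested whether the response to doxycycline differed between the Sox17-inducible lines and KH2. The response of Spink1 was lower in the inducible lines than in KH2 (difference -2.02 ± 0.68, SE), and those of Otx2 (1.82 ± 0.40), Gata6 (1.77 ± 1.02) and Fbln2 (1.27 ± 0.35) were higher. The extraembryonic endoderm core list was the only list called, with 12 of 12 genes higher and a median difference of 0.70 (adjusted p = 0.0183, and 0.820 with an estimated correlation). By fry it was not called (adjusted p = 0.922), and 0 of its genes passed when adjusted over the list alone. No list was called in the authors' values (lowest adjusted p = 0.0613), with the stricter detection filter (0.0695) or without the untreated array of line 1 (0.164), and without the induced array of line 2 only the trophoblast list was. Without the induced array of line 1 there were 4 called lists and without the untreated array of line 2 there were 5, the core list among them. limma called 0 probes (smallest adjusted p = 0.996, with 344 at an unadjusted p under 0.05, and 0 with trend and robust moderation). In simulated data this fit recovered 7.8% of 4-fold changes, against 87.8% in the first comparison. It does not use the pairing of arrays by line; with the line as a block and a doxycycline term, which estimates the same difference on 1 residual degree of freedom, 1262 probes reached an unadjusted p under 0.05 and 0 passed (smallest adjusted p = 0.482). That fit called the core (adjusted p = 1.62e-04), parietal endoderm (0.0156) and basement membrane (0.0156) lists as higher with the preset correlation. By fry the core list was called (0.0459). With an estimated correlation 0 lists were called, but all 24 lists then had the same adjusted p of 0.915. On 1 residual degree of freedom that test could not tell the lists apart.

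The fifth comparison, of the inducible lines with KH2 when both were untreated, showed how the lines differed before induction. Fgf8 read 5.39 and 5.12 in the inducible lines, below detection, and 7.08 in KH2. Pou3f1, a POU-domain gene of the primed epiblast, was lower (-1.55 ± 0.29, SE, n = 2 against 1), as was Myc (-0.70 ± 0.23), while Otx2, of the same list as Pou3f1, was higher by 0.37 ± 0.29. Gsc was detected in KH2 and not in the inducible lines. Called as lower were the Wnt target (6 of 6 genes, median -0.60, adjusted p = 0.000582), mesendoderm (3 of 3, -0.82, 0.00125), fibroblast and feeder cell (7 of 7, -0.61, 0.00666), Nodal target (6 of 6, -0.62, 0.00872), primed epiblast (5 of 7, -0.54, 0.0149) and trophoblast (7 of 9, -0.52, 0.0444) lists. With an estimated correlation each had an adjusted p of 0.811 or more, and fry called 0 (lowest adjusted p = 0.234). Adjusted over the list alone, 2 mesendoderm genes and 1 primed epiblast gene were lower, and 2 lists were called without the dim-probe filter and 3 without the untreated array of line 1. The extraembryonic endoderm core list was not called in this comparison. limma called 0 probes (smallest adjusted p = 0.0888, with 348 at an unadjusted p under 0.05, and 0 with trend and robust moderation).

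The sixth comparison gave the size of the doxycycline response in KH2, on 1 array each and without a test. By their brightest probes, the largest higher genes were Gipc1 (1.60), the adhesion adaptor gene Lims2 (1.59), the troponin gene Tnnc1 (1.41), Emp3 (1.30), the keratin gene Krt7 (1.20) and Vill (1.16). The largest lower genes were the chromatin remodeller gene Smarca1 (-1.74), Zfp280d (-1.64), the RNA-binding protein genes Syncrip (-1.54) and Mbnl1 (-1.38), Zfp608 (-1.49) and Bcl11a (-1.38). Other probes gave 1.15, 0.71 and 0.63 for Gipc1, 0.67 for Lims2 and -0.90 for Syncrip. Smarca1 was lower in the inducible lines too (-0.88 and -1.05), while Vill read -0.04 and 0.04 there. The trophoblast list had the highest median in KH2 (0.69), with Krt19 at 0.94, and the primed epiblast list had -0.53. In KH2, 60 probes were at least 2-fold higher and 192 lower, against 186 and 127 in line 1 and 45 and 44 in line 2. The split depended on scaling: KH2 had 7 and 26 without background modelling, 31 and 280 with median centring and 177 and 332 in the authors' values, and line 1 had 275 and 309 in the authors' values. With a spread pooled from the inducible lines, limma called 0 KH2 probes, with 579 at an unadjusted p under 0.05.

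The lines' responses were also compared across all genes. Over 8605 genes the changes in line 1 and line 2 correlated with Pearson r = 0.328 and Spearman rho = 0.310. Line 1 and KH2 gave 0.178 and 0.173, and line 2 and KH2 gave 0.280 and 0.242. No p is given, since genes are not independent replicates. Among the 23 genes at least 2-fold changed the same way in both lines, the largest mean rises were those of Gata6 (2.06) and Fbp2 (1.65). The largest mean falls were those of Spink1 (-1.78), Pla2g1b (-1.53) and Alox5ap (-1.50).

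**Figure D3:**
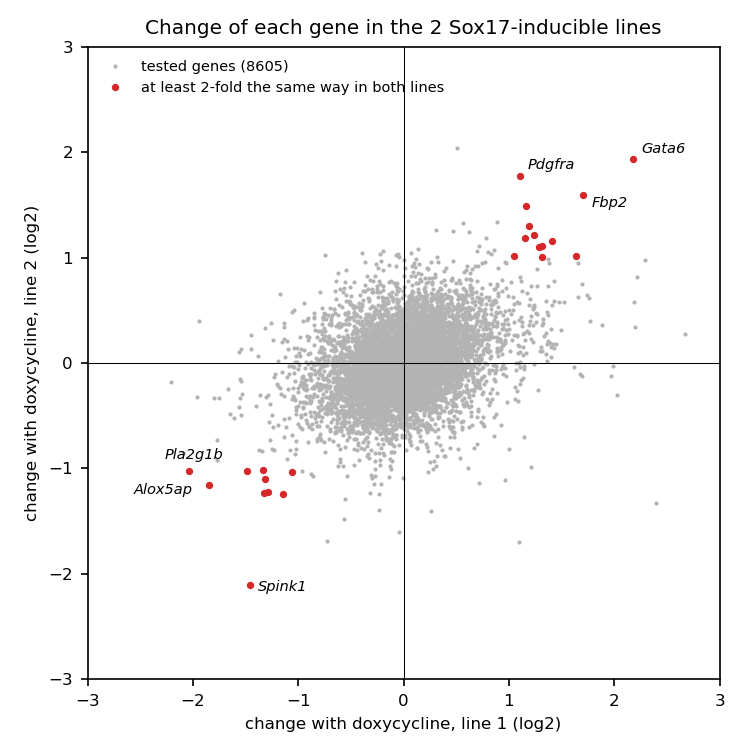
Change with doxycycline (log2) of each of 8605 genes in Sox17-inducible line 1 (horizontal axis) and line 2 (vertical axis), with the 23 genes that were at least 2-fold changed the same way in both lines in red. Gata6 lies farthest out on the higher side at 2.18 and 1.94, and Spink1 at -1.46 and -2.10 on the lower side.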

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

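The tests of doxycycline itself and of RNA integrity for the endoderm list, and the test of Sox17 induction for the Actb probes, were chosen only after the result was seen.

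The response of the extraembryonic endoderm core list differed between the Sox17-inducible lines and KH2 by the test of the difference itself with the preset correlation (adjusted p = 0.0183) and not with an estimated correlation (adjusted p = 0.820), in the authors' values (lowest of any list 0.0613), with the stricter filter (0.0695), without Sox17_untreated replicate 1 (0.164) or without Sox17_dox replicate 2; with the line as a block and a doxycycline term it was 1.62e-04, with 0.0459 by fry and 0.915 with an estimated correlation. Without the block and its term, fry did not call the list (adjusted p = 0.922). The list's median change was 0.99 in line 1 and 0.81 in line 2, against 0.13 in KH2. The normalization between arrays is argued against as the cause of the list's higher values in the inducible lines, since the list's median kept at least 0.786 of its size under 3 other normalizations (0.71, 0.94 and 0.99). Doxycycline itself cannot be told apart from Sox17 induction by that test. The call depended on the settings above, and KH2 had 1 pair of arrays. Its loss with an estimated correlation decides nothing here, since that p rests on 2 residual degrees of freedom. The line block with a doxycycline term left 1, and all 24 lists then had the same adjusted p of 0.915 with an estimated correlation. Uneven RNA integrity stays open too: the list moved in line 2 by 0.817 of its change in line 1, although the Actb probe gap moved by 0.17 there against 1.66 in line 1, but that gap was not shown to read integrity, so the bound set for this test was not used.

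The Actb probes disagreed between arrays, with a range of 2.44 in the gap between the mean of the 3 brighter and the mean of the 2 dimmer probes. For other genes with several tested probes the gap was the brightest probe minus the mean of the rest. Its range had a median of 0.49 over genes, and 0 of 2209 other genes reached 2.44. As the 2 measures differ, these values do not rank Actb among the genes. The 2 dimmer probes read 9.29 to 9.72 in KH2, 10.02 and 10.10 in untreated line 1, 11.95 and 12.16 in induced line 1, and 11.18 to 11.63 in line 2, while the 3 brighter probes read 13.47 to 15.05. Sox17 induction cannot be told apart from other causes: the dimmer probes' rise against the brighter in line 2 was 0.103 of that in line 1, but each line had 1 pair of arrays, and these probes already read 11.18 and 11.47 in untreated line 2. RNA integrity or amplification length may lie behind it too but cannot be told apart from other causes with 6 arrays: the first component of the probe gaps of other genes followed the Actb gap with Pearson r = 0.519 (exact permutation p = 0.301) and Spearman rho = 0.60 (exact permutation p = 0.242). Without the 2 arrays farthest from the median gap r was 0.393.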

How the results depend on the processing

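The alternatives for list counts beyond the first comparison and for genes changed in both lines, and the line block for the difference of responses, were chosen after seeing the data. Of the recomputed summary values 117 stayed the same, while 20 came out weaker or lower, 12 stronger or higher and 8, all correlations, moved. Counts were the same if their totals lay within 1.5 times, whatever the direction of the calls. Correlations were the same if they lay within a 95% bootstrap interval over genes, which are not independent. Of the values for named genes 1206 kept their direction and side of the threshold and 9 turned sign. Another 3, all of Gata6 and 2 of them the same contrast, came to pass. The cause was not tested unless stated. Probes past the threshold numbered 0 wherever an alternative was run, with these exceptions; the fit of the 4 inducible arrays was run for the first comparison only. With the line as a replicate block 1 passed, Gata6 (adjusted p = 0.0437); the same contrast, and so the same 1 probe, results for the comparison with all uninduced arrays, where the KH2 pair then adds nothing to the difference. With a doxycycline term the block estimates the difference of responses, where 0 passed and 3 lists were called, 0 of them with an estimated correlation and 1 by fry. Against all uninduced arrays, 24 passed without Sox17_untreated replicate 2 and 0 without any other array. Of 8 lists called in the first comparison, 0 were called with an estimated correlation or by fry, and 4 (without Sox17_untreated replicate 1) to 11 (without Sox17_dox replicate 1) when an array was left out. Without the block, an estimated correlation and fry also gave 0 lists in the other 4 comparisons. Left-out arrays gave 3 to 7 of 4 lists against KH2 with doxycycline (7 without either Sox17_untreated array), 6 to 11 of 9 against the uninduced arrays, and 3 (without Sox17_untreated replicate 1) to 6 of 6 between untreated lines, where no filter gave 2. For the difference of responses, 1 list in the report, they gave 0 (without Sox17_untreated replicate 1) to 5 (without Sox17_untreated replicate 2), with 4 without Sox17_dox replicate 1; without Sox17_dox replicate 2 the list called was trophoblast. There the authors' values and the stricter filter gave 0, and no filter 4. Of 120 reruns of called lists, 25 lost the call and 0 turned sign; 7 of them were of the cell cycle list (an estimated correlation, fry, the authors' values, and without Sox17_untreated replicate 1, Sox17_dox replicate 2 or either KH2 array). Left-out arrays gave medians of 0.56 to 1.32 for the core, 0.34 to 0.93 for the parietal endoderm, 0.35 to 0.70 for the basement membrane, 0.24 to 0.70 for the stress, 0.15 to 0.37 for the FGF target, 0.25 to 0.92 for the fibroblast, -0.64 to -0.17 for the cholesterol and -0.24 to -0.10 for the cell cycle list; with no filter the FGF target list had 0.13 and the fibroblast list 0.13. Without normexp, 4 genes were 2-fold higher and 1 lower in both lines, all among the 13 and 10; the authors' values gave 29 lower, 10 of them shared. The KH2 count of 252 probes became 33 without normexp, 509 in the authors' values, 1938 at 1.5-fold and 0 by limma with pooled spread. The correlation of lines 1 and 2 moved to 0.363 without normexp, 0.278 with no filter and 0.356 with the stricter filter. That of line 1 and KH2 moved to 0.203, 0.122 in the authors' values and 0.155 with no filter, and that of line 2 and KH2 to 0.238 in the authors' values and 0.237 with no filter. With the line block and a doxycycline term, the changes of Ccne2 (0.20, undetected on the induced arrays), Hmgcs1 (0.32), Top2a (0.42) and Tagln (-0.18) turned sign, since KH2's own response is then taken off. Without Sox17_untreated replicate 1, Acta2 (-0.031), Tagln (-0.036) and Top2a (0.13) did, and without Sox17_dox replicate 2 Tagln (-0.13) against the untreated lines and Stard8 (-0.054) against KH2_dox. The left-out arrays gave -0.031 to 1.42 for Acta2, -0.13 to 1.32 for Tagln, -0.80 to 0.13 for Top2a and -0.054 to 1.72 for Stard8. Some genes that kept their sign also had wide ranges over all alternatives in the first comparison. These were 0.68 to 2.62 for Fbp2, 0.091 to 2.56 for Htra1, 0.086 to 2.16 for Lama1 and -2.32 to -0.038 for Lefty2. Depth on these arrays is signal over background: probes detected on fewer than 2 arrays, those of Sox17 among them, were not tested.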

Other observations

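The test of the Y-linked genes was chosen after Eif2s3y was seen and before the other Y-linked genes were looked at, and its printed value was chosen after the outcome was seen.

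The remaining lists were not called in the first comparison. The median was 0.01 for ribosomal protein genes (adjusted p = 0.768), -0.04 for glycolysis (0.767), -0.02 for epithelial junction genes (0.767), -0.17 for Wnt targets (0.497) and -0.28 for Nodal targets (0.302). The endoplasmic reticulum folding list had a median of -0.0024 and a mean of 0.03, which differ in sign (adjusted p = 0.865), and its median was -0.31 in KH2, where the chaperone gene Hsp90b1 was at -0.93. The p53 and apoptosis list (median -0.20, adjusted p = 0.497) went opposite ways in the inducible lines, at -0.55 in line 1 and 0.18 in line 2, with the cell cycle inhibitor gene Cdkn1a at -0.76 and 0.07. That difference between the lines was not tested.

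Eif2s3y, a Y-linked translation factor gene chosen after its values were seen, was detected on both KH2 arrays (6.97 and 7.91) and on none of the 4 arrays of the Sox17-inducible lines (4.70 to 4.94), at least 3.41-fold lower in those lines. Loss of the Y chromosome in the inducible lines would be a candidate explanation. Uty was the only other listed Y-linked gene with a probe detected on both KH2 arrays (1 of 8 probes over 7 genes). It met the bound set beforehand against that explanation. Its probe was detected on all 6 arrays and was lower in the inducible lines by 0.355 only (6.85 in KH2 against 6.49 ± 0.07, SD, n = 4). Whether that probe also reads an X-linked relative was not tested. The other probes were undetected in KH2 too and could not show a loss, so the explanation stays open.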
